A study of Mus musculus with 2 samples.

How the data were processed

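RNA was measured in dorsal skin of aged C57BL/6 mice, 18 to 20 months old, that were either left untreated or irradiated with red light at 8 J/cm² daily for 28 days. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads, and libraries were made with an NEBNext Ultra RNA kit; strand-specific counting is not stated. GEO describes 2 samples, 1 per group. The deposited table gives the authors' mean FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for each group and an UP or DOWN label for each gene, per the file headers. The submitters' processing notes name Bowtie2 2.2.8, RSEM, R 4.3.1 and DESeq2 1.40.2, without their roles. The genome build is not given in the sources used here, so no coordinates are printed. The criteria by which the authors chose the listed genes are not given either, and the table carries no p-value.

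The table held 4183 rows with 4181 distinct symbols; 2 symbols, Gcat and Nnt, appeared more than once with different values. All value columns were used. Leaving aside the 6 genes described next, the smallest difference was 2.001-fold in both directions, so the table lists only genes that differed by at least about that much, and a gene outside it says nothing about its change. Every mean was a value that an average of 3 numbers with 2 decimals can take, but the number of libraries behind each mean is not stated and single library values were not used here. No spread between animals is therefore available for any value, no replicate check could be made, and no p-value is given. Read depth is unknown because the values are FPKM and not counts, so no intervals or detection floors are given. FPKM is a relative scale: a large amount of RNA from a few genes lowers the values of all others.

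As deposited, nearly all rows fell in order of the ratio of the means within each label. That the authors sorted them so is inferred from this order and is not stated. The order was checked here with a mean of 0 treated as 0.001. A row was called out of order when its log2 ratio lay more than 0.01 outside the range of the 5 rows on each side. This held for 6 rows, Col5a1, Col1a1, Tgfb1, Col3a1, Col4a5 and Col5a2. With these removed, the largest step against the order was 0.0022 on the log2 scale. In 120 rows displaced at random in simulated tables of 4183 rows, the check found 120 and called 0 others. These tables were otherwise perfectly sorted and the displacements far exceeded 0.01, so this shows only that the check works as written. The printed means of the 6 genes and their label or position therefore disagree; their direction is left undetermined and the reason is not known.

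Changes are the ratio of the authors' red light mean to the untreated mean, without a pseudocount. A gene at 0 in either group is listed as such and has no fold, and ranks beyond all others in medians. Genes higher and lower were counted by the authors' label. The 38 gene lists were fixed before the data were examined. For each, the members in the table were counted by the direction of their means, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size drawn from the table and matched on mean expression in deciles. A percentile describes this table only, and lists with fewer than 3 members give members only. Lists share genes: 8 of the 39 macrophage genes, 6 of 84 muscle, 5 of 30 T cell, 4 of 20 matrix protease, 4 of 20 complement and 4 of 13 dermal fibroblast genes stand in another list, as do 3 each of the WNT, hair cycle, sebocyte, neutrophil and basal keratinocyte genes. In a check on simulated data, 6 of 100 unshifted lists of 20 genes fell outside percentiles 2.5 to 97.5, and 29 of 100 lists shifted by 2 on the log2 scale lay above 97.5, so a middling percentile does not exclude a shift of that size. Named genes follow a rule also fixed beforehand: among genes of at least 1 FPKM in either group whose symbol is not a predicted-gene or clone name, the 10 largest rises and the 10 largest falls, plus the 2 members of each list with the largest change. A planned comparison of single library columns could not be made. Symbols were looked up in RefSeq (GRCm38.p6) and GENCODE M21 names, where 4143 were found and 38 were not. Mean transcript lengths, used only to weight shares of FPKM, came from GENCODE M21. Alternatives were a stricter fold, an expression minimum of 1 FPKM, pseudocounts of 1 and 0.1, and unmatched random lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.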

Results

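Dorsal skin from untreated aged mice was compared with dorsal skin from aged mice given daily red light, to ask which genes differ after irradiation intended to lessen age-related skin degeneration. The values are the authors' mean FPKM per group, from 1 GEO sample per group, with no spread, so no difference below could be set against the variation between animals. The authors' table listed 1613 genes as higher and 2570 as lower after red light, 38.6% of them higher. Genes labelled higher had a median difference of 3.74-fold and those labelled lower of 3.09-fold. The large differences lay on the higher side, where 219 genes differed by at least 100-fold or had a mean of 0 in untreated skin, against 15 such genes among those labelled lower. Of the 36 fixed lists with at least 3 listed members, 5 had a median above 0 and 31 a median below 0.

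Genes of the hair shaft and inner root sheath, the keratinized parts that a growing follicle makes, showed the largest difference. All 93 listed members were higher after red light, with a median of 340-fold (log2 8.41, or 7.52 with a pseudocount of 1) and a percentile of 100. Their FPKM summed to 278 in untreated skin and 75124 in red light skin, or 0.219% and 44.98% of the FPKM of all listed genes. The list's 2 members named by the rule, Crisp1 and Krtap5-3, were listed at 0 in untreated skin and at 9.50 and 2.03 FPKM after red light. Krtap24-1, a keratin-associated protein, went from 0.0867 to 76.2 FPKM. Krt71, an inner root sheath keratin chosen after its values were seen, went from 14.9 to 4460 FPKM. Keratin-associated genes are near-identical to one another, so the share of reads given to each is uncertain.

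Most listed proliferation, hair cycle, WNT and melanocyte genes were higher as well. Of 93 listed proliferation genes, 92 were higher, with a median of 4.41-fold (log2 2.14, or 1.32 with a pseudocount of 1) and a percentile of 100; the exception, H2ac18, is a histone gene that went from 23.9 to 9.27 FPKM. The members named by the rule were the histone genes H2bc12, listed at 0 in untreated skin and at 0.837 FPKM after red light, and H2ac11, at 0.0567 and 1.99 FPKM. Among hair cycle regulators 20 of 25 were higher, with a median of 3.44-fold (percentile 99.9). Padi1, which converts arginine to citrulline in hair proteins, went from 0.31 to 63.6 FPKM, and Fgf5, a signal that ends hair growth, from 0.127 to 14.03 FPKM. The WNT list had 21 of 31 members higher, with a median of 2.29-fold (percentile 98.9). Lef1, a transcription factor of WNT signalling, was 24.3-fold higher, while the WNT-binding Sfrp4 was 8.96-fold lower. Of 13 melanocyte genes 12 were higher, with a median of 35.6-fold and a percentile of 100. With a pseudocount of 1 the median log2 ratio was 2.13 in place of 5.15. Oca2 and Mc1r, the members with the largest change, went from 0.0167 to 3.46 and from 0.0133 to 1.53 FPKM.

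**Figure D1:**
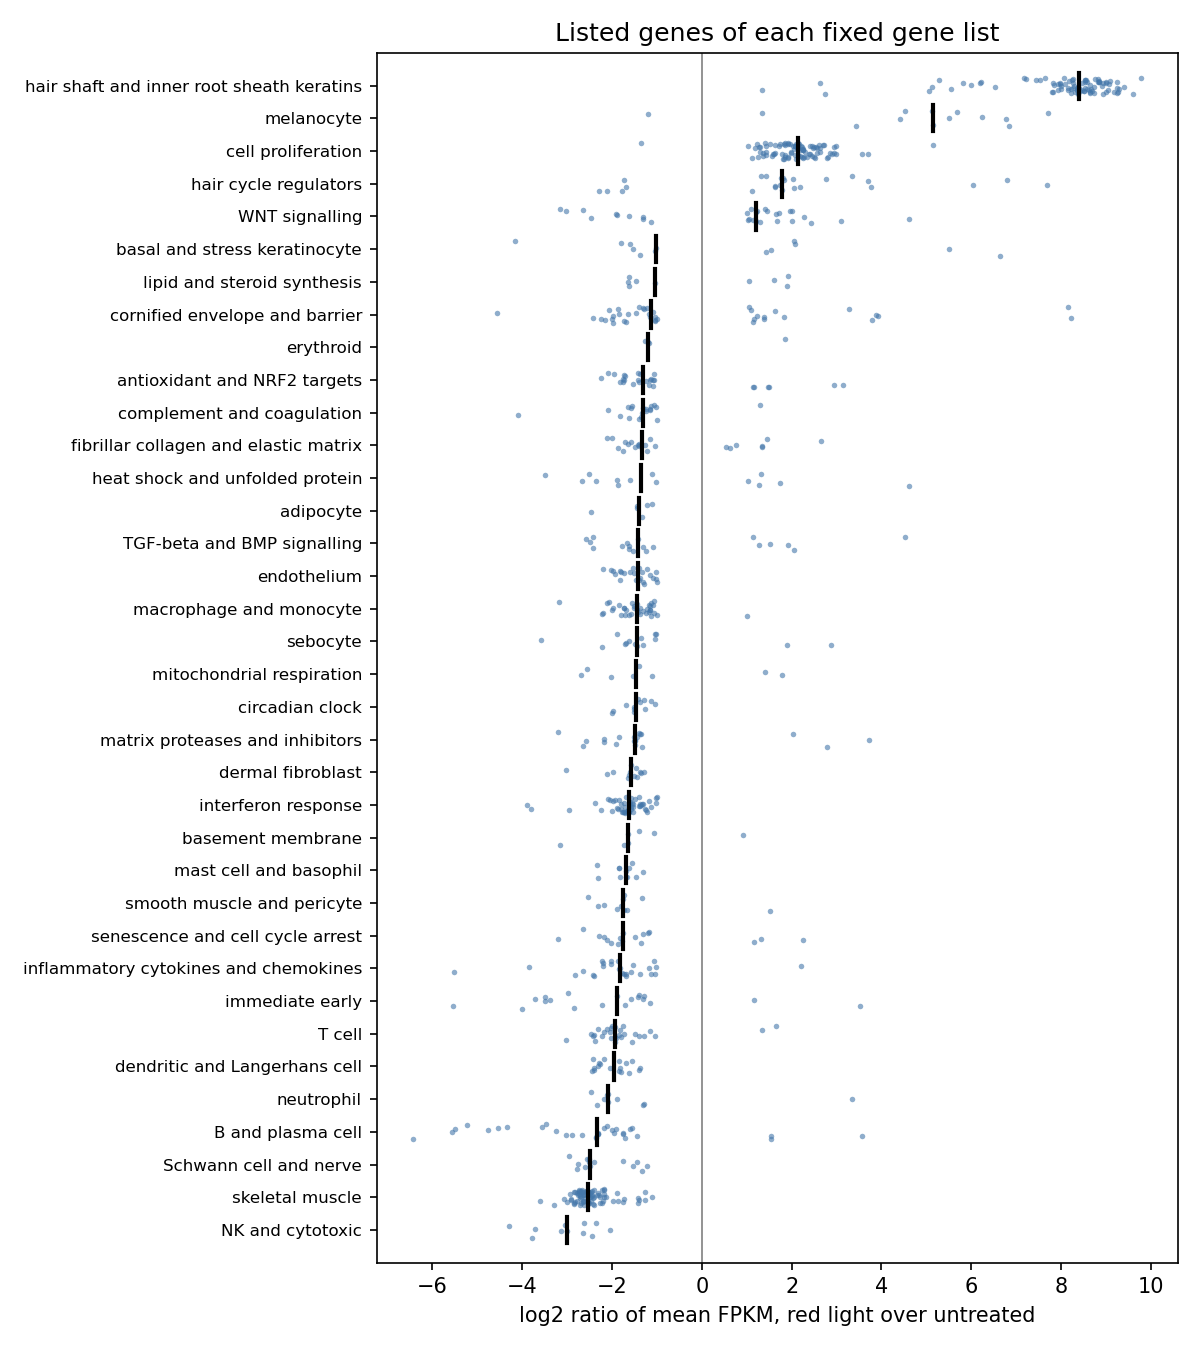
Log2 ratio of the authors' mean FPKM, red light over untreated, for each listed gene (points) of the 36 gene lists with at least 3 members, with list medians as black bars; genes with a mean of 0 in either group are counted in the medians but not drawn. Medians lie above 0 in 5 lists and below 0 in 31, and no point falls near 0 except the genes out of the table's order, because the table lists only genes that differed by about 2-fold or more.

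Epidermal genes went both ways. In the cornified envelope and barrier list 15 of 40 members were higher, with a median log2 ratio of −1.13 (percentile 39.1). The 2 with the largest change were the trichohyalin genes Tchhl1 and Tchh, which also serve the inner root sheath, at 297-fold and 283-fold higher. Krt10, a keratin of the upper epidermis, and Lor, a main cornified envelope protein, both chosen after their values were seen, were 4.21-fold and 3.60-fold lower. Of the envelope families, also picked out afterwards, all 3 listed Sprr genes were higher, by a median of 13.7-fold with Sprr1a going from 215 to 2092 FPKM, and all 10 listed Lce genes were lower, by a median of 2.56-fold. Of 13 basal and stress keratinocyte genes 6 were higher and 7 lower, with a median of −1.02 (percentile 67.1), while their summed FPKM was higher, at 2665 against 1316. S100a7a went from 1.03 to 102.8 FPKM and the follicle keratin Krt75 from 6.84 to 311 FPKM. Sebocyte genes were lower in 13 of 15 (median −1.45, percentile 7.49). Scd3, a fatty acid desaturase, was 11.96-fold lower and Pm20d1 7.30-fold higher. In the lipid and steroid synthesis list 4 of 9 were higher (median −1.03, percentile 63.6), among them the desaturases Fads3 and Fads2 at 3.78-fold and 3.74-fold.

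Skeletal muscle genes, which the thin muscle sheet under mouse skin expresses, were lower in 84 of 84 cases, with a median of 5.78-fold and a percentile of 0. Their summed FPKM was 26897 in untreated and 4993 in red light skin, or 21.2% and 2.99% of the listed total. Myh3, a myosin heavy chain, was 12.2-fold lower, but at low levels, from 0.53 to 0.0433 FPKM. With a pseudocount of 1 its log2 ratio was −0.55 in place of −3.61. Trim63, a ubiquitin ligase of muscle, was 9.79-fold lower. The Schwann cell and nerve list was lower in 14 of 14 (median 5.65-fold, log2 −2.50 or −1.48 with a pseudocount of 1, percentile 0), with Cdh19 at 7.71-fold and the myelin gene Mag at 6.90-fold. Smooth muscle and pericyte genes were lower in 10 of 11 (median −1.75, percentile 0.80). Des, which also stands in the skeletal muscle list, and Synpo2 were 5.83-fold and 4.98-fold lower. Mitochondrial respiration genes were lower in 6 of 8 (median −1.46, percentile 13.4), led by the muscle forms Ckmt2 and Cox6a2 at 6.49-fold and 5.89-fold. Of these 8 genes 4 also stand in another list, Ckmt2, Cox6a2, Cox8b and Ucp3 in that of muscle, and the list's summed FPKM was higher after red light, at 1570 against 962. In the erythroid list 3 of 4 were lower (median −1.19, percentile 38.7), including Hbb-bs at 2.41-fold, while Slc4a1 was 3.63-fold higher. These falls stood in the same table as the rise of the 93 hair list genes, which took up 44.98% of the listed FPKM after red light.

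**Figure D2:**
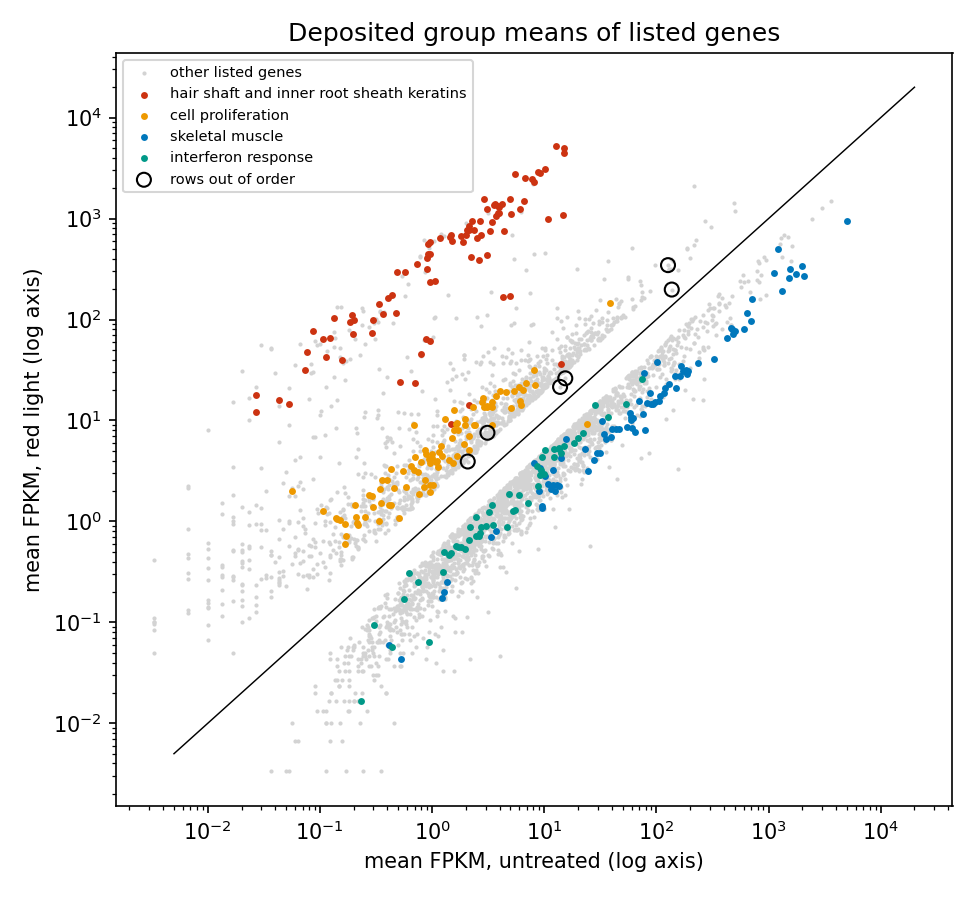
The authors' mean FPKM in untreated skin (x, log axis) against red light skin (y, log axis) for each listed gene with both means above 0, with 4 gene lists coloured and the 6 genes out of the table's order circled; the line marks equal means. The hair list lies far above the line and the 84 muscle genes lie below it.

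Most listed vessel, connective tissue and fat genes were lower, but none of the lists in this paragraph reached the lowest 2.5 percentiles of random lists. All 24 endothelial genes were lower (median 2.70-fold, percentile 4.35), with the tight junction gene Cldn5 at 4.62-fold and Mmrn1 at 4.06-fold. All 13 dermal fibroblast genes were lower (median 2.97-fold, percentile 4.02), with Sfrp2 at 8.12-fold and Pdgfrl at 4.301-fold. All 6 adipocyte genes were lower (median 2.63-fold, percentile 17.9), with Sfrp5 at 5.50-fold and Acacb at 2.74-fold; 3 of the 6 (Ucp3, Cidea and Sfrp5) also stand in another list. Matrix proteases and their inhibitors were lower in 17 of 20 (median −1.49, percentile 6.84); the collagenase Mmp13 was 9.18-fold lower and Adamts18 was 13.1-fold higher. Complement and coagulation genes were lower in 19 of 20 (median −1.31, percentile 13.4), with C7 at 17.1-fold and F7 at 4.26-fold. The levels of F7 were low, at 0.597 and 0.14 FPKM.

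Collagen and TGF-beta genes hold the 6 rows whose means disagree with their label or place in the table. By their means 15 of 22 fibrillar collagen and elastic matrix genes were lower, with a median log2 ratio of −1.33 (percentile 8.67), and without the 4 of them out of order 15 of 18, with a median of −1.41. Pcolce2, an enhancer of procollagen processing, was 4.33-fold lower and Plod2, which modifies collagen lysines, 6.26-fold higher. Basement membrane genes were lower in 6 of 7 (median −1.63, percentile 7.59), and in 6 of 6 without Col4a5 (median −1.64). Lama1 was 8.97-fold lower, from 0.957 to 0.107 FPKM, and Lamb2 3.33-fold lower. TGF-beta and BMP genes were lower in 13 of 19 (median −1.42, percentile 9.99), and in 13 of 18 without Tgfb1 (median −1.48); Ccn1 was 5.93-fold lower and Bmp8a 23.1-fold higher. The means of Col3a1 (137 and 198 FPKM), Col4a5 (2.08 and 3.92), Col5a2 (13.8 and 21.5) and Tgfb1 (3.12 and 7.55) were higher after red light, yet all 4 were labelled as lower. Col1a1 (126.9 and 346 FPKM) and Col5a1 (15.4 and 26.2 FPKM) were labelled as higher, but stood among genes with ratios near 6.40-fold and 12.2-fold, against 2.72-fold and 1.70-fold from their own means. The direction and size of these 6 genes are not taken as known.

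**Figure D3:**
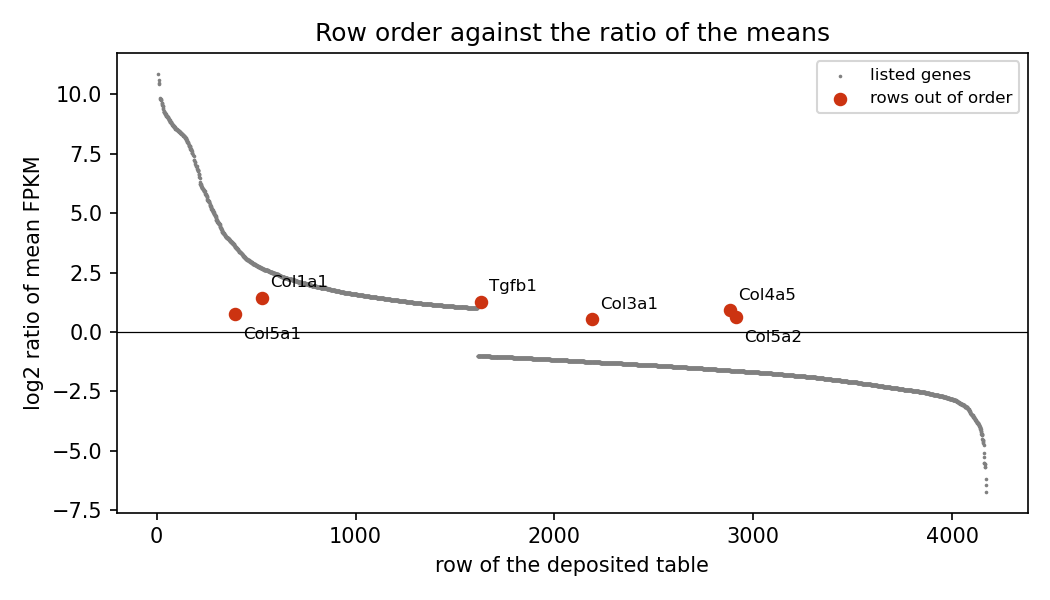
Log2 ratio of the authors' mean FPKM (y) against the row of the table (x) for each listed gene with both means above 0, with the 6 genes out of order in red. All other rows follow the falling order within each label to 0.0022 on the log2 scale, while Tgfb1, Col3a1, Col4a5 and Col5a2 lie above 0 among genes labelled lower.

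Immune cell genes were mostly lower, beside the lower muscle, nerve and vessel genes. T cell genes were lower in 28 of 30 (median 3.82-fold, log2 −1.93 or −0.85 with a pseudocount of 1, percentile 0.06). Trat1 was 8.09-fold lower, from 0.62 to 0.0767 FPKM, and Cd96 5.54-fold lower. The 2 higher members, Gata3 and Tcf7, held much of the signal, and the summed FPKM was 113 and 84.7. All 11 NK and cytotoxic genes were lower (median 8.00-fold, percentile 0), though at low levels, and with a pseudocount of 1 the median log2 ratio was −1.06 in place of −3.00; Klrb1c went from 0.39 to 0.020 FPKM and Fasl from 0.183 to 0.0133 FPKM. B and plasma cell genes were lower in 31 of 34 (median 5.04-fold, log2 −2.33 or −1.29 with a pseudocount of 1, percentile 0), with Ighv1-78 and Ighv5-4 at 1.63 and 0.63 FPKM in untreated skin and listed at 0 after red light. The list's summed FPKM differed little, at 543 and 484, because of its 3 higher members: Sdc1, which epithelia also express, went from 136 to 394 FPKM, Tnfrsf13c from 0.253 to 3.02 and Derl3 from 0.277 to 0.803. Immunoglobulin variable genes resemble one another closely, so their single values are uncertain. Macrophage and monocyte genes were lower in 38 of 39 (median 2.72-fold, percentile 2.26), with Retnla at 9.02-fold and Lyz1 at 4.70-fold. Neutrophil genes were lower in 9 of 10 (median 4.25-fold, log2 −2.09 or −1.06 with a pseudocount of 1, percentile 0.25), with Camp at 5.52-fold lower and Padi4 at 10.2-fold higher. All 12 mast cell and basophil genes were lower (median 3.23-fold, percentile 3.09), with the histamine-forming Hdc at 5.07-fold and Ms4a2 at 5-fold. All 18 dendritic and Langerhans cell genes were lower (median 3.85-fold, percentile 0.09), with H2-Eb1 at 5.43-fold and Flt3 at 5.40-fold.

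Interferon response genes were lower in 52 of 52 cases, with a median of 3.08-fold (log2 −1.62, or −1.04 with a pseudocount of 1) and a percentile of 0.20. Whether hair transcripts, which lower all other values on the FPKM scale, account for this fall was not tested. Gbp10 was 14.9-fold and Ido1 14-fold lower, both under 1 FPKM in both groups. Inflammatory cytokines and chemokines were lower in 26 of 27 (median 3.52-fold, log2 −1.81 or −1.09 with a pseudocount of 1, percentile 0.16), with Il20 going from 0.46 to 0.010 FPKM and Ccl3 from 4.54 to 0.317 FPKM. Of these 27 genes 9 also stand in another list. Senescence and cell cycle arrest genes were lower in 15 of 18 (median 3.40-fold, percentile 0.25), with Mmp13 and Mmp3 at 9.18-fold and 6.30-fold. The 3 higher members were Lmnb1, Cdkn2b and Hmgb2, and 8 of the 18 stand in another list. The list's median is not read as a measure of senescence. Cdkn2a, a cell cycle inhibitor chosen after its values were seen, was 2.79-fold lower, and Cdkn2b, chosen in the same way, 2.49-fold higher.

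Stress and timing genes were mostly lower. Immediate early genes, which respond within minutes to handling and injury, were lower in 17 of 19 (median 3.73-fold, percentile 0.07), with Fosb at 46.7-fold and Fos at 16.1-fold. All 12 circadian clock genes were lower (median 2.77-fold, percentile 8.81), including Per1 at 4.01-fold and Nr1d1 at 3.97-fold; the hour of sampling is not stated. Antioxidant and NRF2 target genes were lower in 22 of 28 (median −1.31, percentile 19.5). The members with the largest change were higher, namely the cystine transporter Slc7a11 at 8.87-fold and Gpx2 at 7.70-fold. Heat shock and unfolded protein genes were lower in 9 of 14 (median −1.36, percentile 14.3), with Chac1 at 24.3-fold higher and Atf3 at 11.3-fold lower. The ribosomal protein list had 2 listed members and the opsin list had 0. Rps23rg1 was 8.00-fold higher, from 0.123 to 0.987 FPKM, and Rpl7l1 2.03-fold higher.

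Among the single largest rises of at least 1 FPKM, Crisp1, Tm4sf4, H2al1a, Krtap5-3, H2al1g, H2al1e and H2al1b were listed at 0 in untreated skin, with Tm4sf4 at 4.62 and H2al1a at 4.50 FPKM after red light. H2al1g, H2al1e and H2al1b, close copies of H2al1a, stood at 1.503, 1.35 and 1.03 FPKM. Kcne1, a potassium channel subunit, was 904-fold higher from 0.0167 FPKM, Krtap24-1 879-fold and Amtn 804-fold. Among the largest falls, Ccl21d, Ighv1-78 and Rnase2a were listed at 0 after red light, from 16.6, 1.63 and 1.21 FPKM. Ighg3 was 86.2-fold, Igkv1-133 46.9-fold, Ighg1 45.2-fold, a further heavy chain variable gene 37.7-fold, Igkv3-7 27.2-fold and Pon1 25.6-fold lower, beside Fosb. Apart from Fosb, all of these were under 1 FPKM after red light, so their folds are uncertain. With a pseudocount of 1 the log2 ratio of Ighg3 was −2.26 in place of −6.43. That of Igkv1-133 was −1.31 in place of −5.55, while Fosb stayed at −5.18. Ccl21d has near-identical copies, so its fall is uncertain.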

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

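The counts and medians without the 6 genes out of order, and the counts taking direction from the means, were chosen after seeing the data; the other alternatives were fixed before. At a log2 ratio of at least 2 the counts were 761 higher and 788 lower, fewer by construction. With a pseudocount of 1, which shrinks the ratios of low genes, 1045 higher and 1516 lower genes kept a log2 ratio of at least 1. With that pseudocount the median log2 ratio was 7.52 for the hair list, 1.32 for proliferation and −1.04 for the interferon response. A minimum of 1 FPKM (1370 and 2186 genes), a pseudocount of 0.1 (1549 and 2440), leaving out the 6 genes (1611 and 2566) and counting by means (1617 and 2566) moved the counts by less than 1.5-fold. A list median was called moved when it changed by over 1.5-fold. With the minimum no list median changed sign, and 31 of 36 were below 0. The medians of the 3 lists that hold the 6 genes also kept their sign when these were left out. With either pseudocount no list median changed sign either. That was largely fixed beforehand, since a pseudocount added to both means cannot change the sign of any gene. List medians were not computed for the stricter ratio. A pseudocount of 1 moved 10 of the 36 medians and 0.1 moved 2. Besides those above, these were with a pseudocount of 1 melanocyte (2.13), nerve (−1.48), T cell (−0.85), NK (−1.06), B and plasma cell (−1.29), neutrophil (−1.06) and cytokine genes (−1.09), and with 0.1 melanocyte (4.04) and NK genes (−2.10). Unmatched random lists took 2 lists out of the lowest 2.5 percentiles, smooth muscle at 4.20 and macrophage at 6.57. Of 77 single genes, 42 moved with a pseudocount of 1 and 21 with 0.1. A pseudocount cannot reverse a single gene, so direction was not tested by it. The stricter FDR was not run because the table has no FDR. The alternatives for single library columns (pseudocount, low-value filter, left-out replicates, replicate block, another count test and its filter) were not run because the table has group means only. No paired analysis was possible because each group has 1 value per gene. Depth is unknown, so how far counting error reaches into genes below 1 FPKM in both groups (627 listed) is open.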

Other observations

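The gene families in this paragraph were chosen after their values were seen. All 10 listed Skint genes, which skin epithelium uses to shape its resident T cells, were lower, by a median of 4.54-fold. So were all 17 listed major histocompatibility complex genes whose symbols begin with H2- (3.46-fold). Genes of that region with other symbols were not counted. All 16 listed gamma protocadherins were lower by a median of 2.44-fold and all 9 voltage-gated sodium channel genes by 4.31-fold. Of 7 zinc transporter genes 6 were higher. Among predicted genes without a given name, 59 were at least 100-fold higher or listed at 0 in untreated skin, and their FPKM summed to 35.0 and 12826. Of the 43 of these that RefSeq (GRCm38.p6) holds as protein-coding, 22 lie next to a keratin or keratin-associated gene, against 0 of 18 among the other predicted genes. Some symbols are not the current mouse names: Akt, an older name of Akt1, went from 34.1 to 251 FPKM, and Nrf2, an older name of Nfe2l2, from 3.55 to 7.16 FPKM.

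All tests of explanations below were chosen after the results were seen. The first pattern is the rise of hair genes. Reads shared among near-identical genes would leave the family's sum in place. Yet the summed FPKM of 74 hair keratins and keratin-associated genes, with Krt33a and Krt33b left out, was 311-fold higher. Cut hair lacks the inner root sheath, which is shed inside the skin. Yet the 7 listed keratins of that sheath were all higher, by a median of 8.36 on the log2 scale. The median of 13 listed shaft keratins, with Krt33a and Krt33b left out, lay −0.14 from that of the sheath. For these some carried-over hair is not excluded. More growing (anagen) follicles in the red light skin could give both, but their test decides nothing: the hair cycle, WNT, melanocyte and proliferation lists had medians above 0 in 4 of 4 cases and were picked because they were the lists that rose. Whether light set the stage of the hair cycle, or it differed by chance, cannot be told apart from 2 values per gene, 1 mean per group.

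The second pattern is the fall of muscle and of other cell types. A dilution of the FPKM scale by hair transcripts lowers every gene by the same factor. The muscle median lay −1.10 and the NK median −1.57 from the endothelial one on the log2 scale. The upper quartile of muscle (−2.28) lay below the lower quartile of endothelium (−1.80). So did that of NK genes (−2.53, or −2.38 among the 6 of at least 1 FPKM). Dilution is therefore not the whole cause for the listed muscle genes. With a pseudocount of 1 the NK median was −1.06, against −1.16 for endothelium and −2.40 for muscle. The NK gap thus depends on low values, and dilution is not excluded for NK genes. The 219 genes at least 100-fold higher or listed at 0 in untreated skin, most of the hair list among them, made up 52.5% of the listed FPKM after red light. On their own they could lower the others by at most 2.10-fold (1.72-fold weighted by transcript length). Hair list genes that rose less, such as Psors1c2 (1087 FPKM after red light) and Krtap3-2 (999 FPKM), are not counted in this limit. Nerve, T cell, B cell, neutrophil and dendritic cell genes had medians of at least 3.82-fold, over 1.5 times that limit. Their upper quartiles were at least 2.75-fold, but decide nothing, since the table's limit of about 2-fold alone puts them near or past 2.10-fold. The medians argue against these 219 genes as the whole cause for the listed genes of these lists, without excluding it. The median of all genes labelled lower was 3.09-fold. The margin is narrowest for T cell genes with a pseudocount of 1. Their median log2 ratio was −0.85, against −0.61 if each were lowered by 2.10-fold. For mast cell genes, with a median of 3.23-fold, and vessel, dermal and macrophage genes, up to 2.97-fold, this cause stays open. The table's limit of about 2-fold leaves only the larger falls of these lists in view. The interferon response list and other lists with falls of this size were not tested. The 1617 genes with higher means could as a whole lower the others by up to 4.21-fold. This covers the mast cell, T cell and dendritic cell medians too. A lower share of muscle in the red light tissue stays open as well: that all 84 genes were lower within an interquartile range of 0.43 restates the pattern and decides nothing.

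The third pattern concerns Hox genes, which keep a record of position along the body; they were picked out after their values were seen. All 6 listed Hox genes of numbers 9 and 10 were lower after red light, by a median of 3.95-fold, with Hoxa10 going from 1.72 to 0.183 FPKM, while 6 of 7 of numbers 1 to 8 were higher; Hoxc13, the highest-numbered one listed and also a regulator of hair keratins, went the other way, from 0.967 to 61.8 FPKM. Fewer dermal fibroblasts could lower the first group: its median lay −0.41 from the fibroblast median on the log2 scale, and 5 of the 6 lay below the fibroblast lower quartile (−1.65), which speaks against this as the whole cause without excluding it. Skin taken from another position along the body could do both, but the 6 higher genes are all of cluster B, and outside it 0 of 1 were higher (Hoxa7 was lower), too few to decide. The place of sampling within the dorsal skin is not stated.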
